A study of Rattus norvegicus with 4 samples.

How the data were processed

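Total RNA was taken from the striata of adult male Wistar rats, 4 in the study. In the irradiated rats a Leksell gamma knife, which focuses gamma rays from outside the head, had delivered a central maximum of 60 Gy over 30 min to 1 striatum through a 4 mm collimator, and the brains were removed 16 h later. Per the labels, 4 two-colour Agilent rat arrays were hybridised. On 2 arrays the irradiated left striatum was set against the left striatum of control rats, and on the other 2 the un-irradiated right striatum of irradiated rats was set against the right striatum of control rats. Within each side the dyes were swapped: array 1 carried the experimental RNA in Cy5 and array 2 carried it in Cy3. Both arrays of a side carry the same replicate number and the same source names, so they were read as a technical dye swap of 1 pair of RNAs. Each side therefore has 1 replicate, and no p-value or standard deviation is given anywhere.

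The deposited value table holds 43628 features on each of the 4 arrays, with no missing value and no value at exactly 0. Per the submitters' processing notes the authors used Agilent Feature Extraction 8.1; its settings are not given in the sources used here. The deposited values were read as log10 ratios of red over green, the form in which that software writes its log ratio, and were converted to log2. The base, direction and centring are not stated with the table. The medians as deposited (log10) were 0.00418 and 0.00444 on left arrays 1 and 2 and 0.00832 and 0.0111 on right arrays 1 and 2. As deposited, the 2 arrays of a dye swap correlated positively across probes, with r = 0.743 on the left and 0.666 on the right but rank correlations of 0.233 and 0.260, to which a dye effect or values already turned would both lead. The direction was chosen on 5654 genes with 2 or more probes: different probes of 1 gene correlated at 0.163 on the left and 0.0865 on the right in the half-difference of the 2 arrays, against 0.0380 and 0.0411 in the half-sum. Over 1000 draws of genes with replacement, a check added after the results were seen, the middle 95% of the gap between the 2 correlations ran from 0.0866 to 0.166 on the left and from 0.00523 to 0.0853 on the right, so the right side rests on this choice less firmly. The values were accordingly taken as not turned, and array 2 of each side was given the opposite sign, so that every value below is log2 of experimental over control RNA. A wrong log base would change the size of every value but no direction; values already turned would change which genes pass, and the direction is not stated with the table. The file gives ratios without spot intensities, so brightness, background and saturation were not used here, and the number of arrays limits the precision.

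Genes were named from GEO's platform annotation as supplied, which can be old, with symbols updated by Entrez identifier from the RefSeq gene table of the GRCr8 assembly. Of the 43628 features, 23535 had 1 gene, 48 had several and were not named, and 20045 had none in that annotation. For 23488 features the gene's identifier was found in the RefSeq table. This gave 14878 genes, 9224 of them with 1 probe. The build behind the array design is not given in the sources used here, so no genome positions are printed. A gene's value on an array is the mean over its probes. For each side the text gives the mean of the 2 arrays and, after ±, the distance of either array from it, which is a technical spread and covers no variation between animals. A probe or gene was counted as higher or lower when it was past 1.5-fold (0.585 on the log2 scale) in the same direction on both arrays. The difference between sides was taken between arrays of the same dye orientation and counted by the same rule, and overlaps are given beside the number expected of independent lists.

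Before the data were examined, 34 gene lists were fixed: p53 targets, DNA repair, cell cycle, immediate early genes, cytokines and chemokines, interferon response, antigen presentation, reactive astrocyte and acute phase genes, heat shock and unfolded protein response, oxidative stress, glucocorticoid response, circadian clock, apoptosis, growth factors, extracellular matrix, glutamate and GABA receptors, ion channels, ribosomal proteins, the respiratory chain, olfactory receptors, keratins, and markers of astrocytes, microglia, oligodendrocytes and their precursors, endothelium, choroid plexus, cortex, thalamus with septum and hypothalamus, pituitary and other tissue, blood, meninges, striatal projection neurons, and striatal interneurons with monoamine neurons. For each list the members that passed were counted, and the median of its members was placed among the medians of 10000 random gene lists of the same size, as a percentile that describes these arrays and is no test. Random lists were not matched on expression, because no intensities were given. Lists matched on the half-range, which is the distance given after ± and holds dye effect and noise, served as an alternative. The naming rule, fixed at the same time, took per side the 12 top-ranked genes in each direction by the smaller of their 2 array values, up to 4 members per list, the 8 top genes each way for the difference between sides, 8 higher on both sides, 8 lower on both sides and 8 opposite, leaving out placeholder symbols, and 13 genes regardless of their values (Cdkn1a, Mdm2, Ccng1, Bax, Gfap, Fos, Hmox1, Drd1, Drd2, Penk, Tac1, Ppp1r1b, Ttr). Icam1, Cxcl12, Mx1, Bbc3, Adora2a, Adcy5, Nrgn, Neurod6, Steap4, Osmr and the genes first named in the closing section were added after their values were seen.

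The counting rule was tested on simulated arrays with normal noise of 1 width for all probes, set from the median spread of the real ones, and 200 of 43628 probes changed. Of 50 probes changed 1.5-fold it found 8 on each side, and of 50 changed 2-fold 28 on the left and 26 on the right. Of 50 changed 4-fold it found 49 and 46, and of 43428 unchanged probes it counted 146 and 128. In this setting changes of 1.5-fold were mostly missed. Real probes differ in noise, so the shares found need not hold for them, and the last 2 counts are no estimate of chance. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the fold threshold, the use of both arrays or 1, centring, scaling and quantile normalization, noisy and control-like probes, the log base and the way probes are combined into genes. No sample was left out.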

Results

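Expression was measured in the striatum, the input nucleus of the basal ganglia, 16 h after gamma knife irradiation of the left side. The irradiated left striatum and the un-irradiated right striatum of the irradiated rats were each compared with the same side of control rats, with 2 arrays of swapped dyes per side and 43628 features on every array. Values are log2 of experimental over control RNA, as the mean of the 2 arrays ± the distance of either array from it. There is 1 replicate per side, so no value carries an error between animals and no difference was tested.

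The first comparison asks what irradiation left in the targeted striatum. Some targets of p53, the transcription factor activated by DNA damage, were among the genes furthest above control. Fas, a death receptor, was 2.39 ± 0.13 above control, Ccng1 (cyclin G1) 2.0 ± 0.01 and Cdkn1a, the cyclin-dependent kinase inhibitor p21, 2.01 ± 0.04. The DNA repair gene Mgmt, which removes alkyl groups from guanine, was 2.37 ± 0.03 above control. P2ry12, the ADP receptor of resting microglia, fell by 2.67 (± 0.24), and Pdgfra, the growth factor receptor of oligodendrocyte precursors, fell by 2.45 (± 0.13).

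Of 29 p53 targets measured on the left, 6 passed the 1.5-fold rule upward and 0 downward, and the list's median of 0.30 lay above all 10000 random lists. Besides the 3 named above these were Phlda3, an inhibitor of Akt signalling, at 1.84 ± 0.40, the proapoptotic Bbc3 (Puma) at 1.5 ± 0.19 and Bax at 0.77 ± 0.01. Mdm2, the ubiquitin ligase that degrades p53, had a mean of 0.77 ± 0.28 over 3 probes and did not pass, but did with RefSeq mRNA probes alone (0.94) and with its best probe (1.38). Of 29 apoptosis genes 4 passed upward and 0 downward (median 0.20, percentile 99.99). They included Ripk3, a kinase of necroptosis, at 1.10 ± 0.25 and Birc3, an inhibitor of apoptosis, at 1.01 ± 0.25, beside Fas and Bax, which the p53 list also holds. Mgmt was the 1 of 22 DNA repair genes that passed, and that list's median was 0.08 (percentile 90.9, and 98.3 on array 1 alone). Heat shock and unfolded protein response genes had a median of 0.25, above all random lists, although 1 of 24 passed: the small heat shock protein Hspb1 at 0.68 ± 0.02.

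Of 33 cytokine, chemokine and adhesion genes 5 passed upward and 1 downward, with a median of 0.13 (percentile 99.6). Ccl3, which attracts monocytes, stood at 2.08 ± 0.09, Cxcl1, which attracts neutrophils, at 1.70 ± 0.01, interleukin 1 beta (Il1b) at 1.08 ± 0.01 and the adhesion molecule Icam1 at 0.85 ± 0.02. The fifth, Ccl2, averaged 1.66 ± 0.17, but its 3 probes ranged from -0.06 to 4.33 and the median over them did not pass. The probe at 4.33 was its RefSeq mRNA probe, which passed at 3.95 and 4.71 on arrays 1 and 2. Cxcl12, a chemokine made constitutively in brain, was the member that fell, by 0.75 (± 0.15). Of 32 interferon response genes 5 passed upward and 0 downward, and their median of 0.34 lay above all random lists. The ubiquitin-like Isg15 was 1.80 ± 0.16, the guanylate-binding Gbp2 1.49 ± 0.11, the transcription factor Irf7 1.14 ± 0.26, the double-stranded RNA kinase Eif2ak2 0.79 ± 0.02 and the antiviral Mx1 0.62 ± 0.00. Among 23 antigen presentation genes (median 0.23, percentile 99.97) the 3 that passed upward were class I genes, RT1-CE16 at 1.38 ± 0.07, RT1-A2 at 1.01 ± 0.12 and RT1-S3 at 0.64 ± 0.01; near-identical sequences in this family leave open which copy a probe reads. The cysteine protease Ctss, held by this list and by the microglia list, fell by 0.79 (± 0.09).

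Of 27 genes of reactive astrocytes and the acute phase 9 passed upward and 1 downward, and the median of 0.36 lay above all random lists. The transcription factors Cebpd and Cebpb stood at 1.92 ± 0.15 and 0.95 ± 0.10. The S100 family member S100a10 stood at 0.88 ± 0.05 and the asparaginase Aspg at 0.87 ± 0.01. Gfap, the intermediate filament of astrocytes, stood at 1.16 ± 0.40. Steap4, a metalloreductase, was the member that fell, by 1.26 (± 0.63). Of 16 genes on the general astrocyte list 2 passed, both downward. They were the connexin Gjb6, which fell by 0.77 (± 0.04), and the transporter Slco1c1, which fell by 0.66 (± 0.01). Whether its members are expressed in other cell types too was not checked. That list's median of -0.34 lay below all random lists. The 25 microglia and macrophage markers had a median of -0.20 (percentile 0.02). P2ry12, Ctss and the complement subunit C1qa passed downward, the last at -0.79 ± 0.09, whereas Gpnmb, a glycoprotein of activated phagocytes, passed upward at 1.24 ± 0.24 and the Fc receptor Fcgr2b at 0.84 ± 0.06.

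Oligodendrocyte precursor markers fell in 4 of 15 measured members and rose in 0 (median -0.19, percentile 0.36). Beside Pdgfra these were the sialidase Neu4 at -1.45 ± 0.08, Bcas1 at -0.93 ± 0.19 and the proteoglycan versican (Vcan) at -0.91 ± 0.07, whose 3 probes ranged from -1.50 to 0.01. Of 19 oligodendrocyte markers the transcription factor Olig1 passed, at -0.87 ± 0.01, and the median of -0.28 lay below all random lists. The 28 endothelial and pericyte markers had a median of -0.24, again below all random lists, with 0 passing. Of 16 meningeal and fibroblast markers 3 fell and 0 rose (median -0.32, below all random lists): the transcription factor Foxc1 at -1.55 ± 0.63, decorin (Dcn) at -1.07 ± 0.25 and osteoglycin (Ogn) at -0.76 ± 0.17. The 25 markers of striatal projection neurons, the dopamine-responsive output cells, had a median of -0.27, below all random lists. The signalling regulator Rgs9 passed at -0.81 ± 0.03, whereas the dopamine receptors Drd1 and Drd2 had means of 0.13 ± 0.07 and -0.16 ± 0.04, the neuropeptide precursors Penk and Tac1 -0.19 ± 0.31 and -0.13 ± 0.17, and Ppp1r1b (DARPP-32) -0.67 ± 0.70. None of those 5 passed.

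Of 26 cell cycle genes 1 passed, thymidylate synthase (Tyms) at 1.55 ± 0.20, while the list's median was -0.18 (percentile 0.02). The 25 immediate early genes had a median of -0.11 (percentile 1.76) and a mean of 0.13, of the opposite sign. The stress-induced factor Atf3 at 2.87 ± 0.83 and Fos at 1.10 ± 0.27 were the 2 that passed. The remaining top-ranked genes above control were Tnfsf9, the ligand of a T cell costimulatory receptor, at 3.42 ± 0.41, Fignl1, an ATPase of recombination repair, at 2.44 ± 0.21, the NF-kappaB cofactor Bcl3 at 2.39 ± 0.01, the phospholipase Pla1a at 2.27 ± 0.08 and the rhomboid protease Rhbdl2 at 1.85 ± 0.01. Those below were the chromatin protein Hmga2 at -2.01 ± 0.38, the primase-associated subunit Pola2 at -1.87 ± 0.05, Zp3r at -1.79 ± 0.09, the decoy chemokine receptor Ackr2 at -1.74 ± 0.33, Tmem255b at -1.73 ± 0.06, Fam89a at -1.54 ± 0.16, and 3 genes of large receptor families, Ly49s7, Or10d5j and Vom2r44, at -1.64 ± 0.12, -1.59 ± 0.19 and -2.12 ± 0.77.

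In all, 640 probes were higher and 603 lower on the left, and 175 genes were higher and 153 lower of 14878. Shuffling the probes of 1 array, planned as a chance count, gave 1193 probes either way as the mean of 100 shuffles, beside the 1243 observed. It breaks up the dye effect, which drives the 2 turned arrays in opposite directions, and this would overstate chance. It also breaks up noise that a probe has on both arrays, and this would understate it. Which of these weighs more was not tested, so the shuffle is no measure of chance. Array 1 alone put 6269 probes higher and 5031 lower, and array 2 alone 4173 and 5142, with the dye effect included. On array 2 alone the cytokine list stood at percentile 90.5 and the cell cycle list at 16.7, on array 1 alone the oligodendrocyte precursor list at 4.49, and the immediate early list stood at 19.9 and 6.25 on arrays 1 and 2; RefSeq mRNA probes alone put the cytokine list at 92.2 and the immediate early list at 5.35, which the best probe put at 2.88. The probes of some passing genes were far apart on the left, from 0.10 to 2.13 for Il1b, 0.26 to 1.70 for Irf7, 0.30 to 2.18 for Gpnmb, 1.38 to 2.64 for Cdkn1a and -1.73 to -0.41 for Dcn. With RefSeq mRNA probes alone Gfap, Hspb1, Dcn, Ggta1 and Krt10 no longer passed on the left and Slc17a7 did (0.82), and with the best probe Hspa1a did (0.92).

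**Figure D1:**
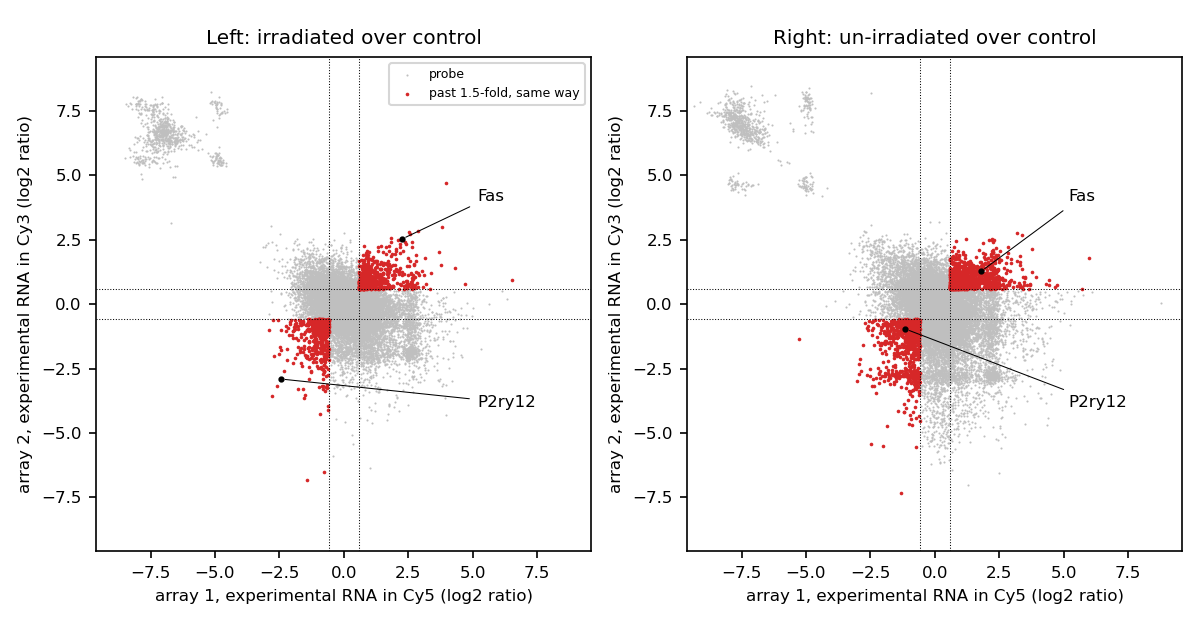
Log2 of experimental over control RNA on array 1 (horizontal, experimental RNA in Cy5) against array 2 (vertical, experimental RNA in Cy3) for all 43628 features, left side in the left panel and right side in the right panel. Red points passed 1.5-fold (dotted lines) the same way on both arrays, and black points are the gene values of Fas and P2ry12. The grey cloud at upper left holds 726 features that followed the dye on all 4 arrays, 0 of them with a gene.

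The second comparison asks what differed in the striatum that was not targeted. On the un-irradiated right, 3 of 14 cortex markers and 4 of 16 meningeal markers passed upward, and 7 of 25 striatal projection neuron markers downward. Neurod2, a transcription factor of cortical excitatory neurons, was 1.95 ± 0.23 above control, and fibromodulin (Fmod), a collagen-binding proteoglycan, 1.28 ± 0.22. The transcription factor Foxp1 of projection neurons fell by 0.96 (± 0.05). Part of the p53 targets were also higher: Fas at 1.54 ± 0.26, Cdkn1a at 1.48 ± 0.44 and Ccng1 at 1.33 ± 0.02.

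Of 25 striatal projection neuron markers 7 fell and 0 rose on the right, and the median of -0.63 lay below all random lists. Besides Foxp1 these were the orphan receptor Gpr6 at -0.82 ± 0.14, the adenosine receptor Adora2a at -0.77 ± 0.18, Rgs9 at -0.75 ± 0.02, prodynorphin (Pdyn) at -0.74 ± 0.06, the adenylyl cyclase Adcy5 at -0.68 ± 0.09 and the dopamine receptor Drd1 at -0.63 ± 0.01, which no longer passed once each array was centred. Drd2, Tac1, Penk and Ppp1r1b had means of -0.45 ± 0.06, -0.69 ± 0.14, -0.46 ± 0.12 and -0.86 ± 0.61 and did not pass. Of 14 cortex markers 3 rose and 0 fell (median 0.36, percentile 99.98, and 97.1 on array 1 alone). They were Neurod2, the related Neurod1 at 1.41 ± 0.45 and the vesicular glutamate transporter Slc17a7 at 1.21 ± 0.23; Neurod6 had 0.71 ± 0.45, Nrgn 0.06 ± 0.16 and Emx2 -0.27 ± 0.23. Of 16 meningeal and fibroblast markers 4 rose and 0 fell, and the median of 0.34 lay above all random lists. Beside Fmod these were the retinoic acid enzyme Aldh1a2 at 1.33 ± 0.45, Ogn at 1.06 ± 0.20 and Igf2 at 0.86 ± 0.26, which centring likewise ended. Oligodendrocyte markers had a median of -0.38 (percentile 0.01) with 0 of 19 passing. Medians of the other glial and vascular lists on this side were -0.09 for astrocytes with 0 of 16 passing, -0.04 for microglia with P2ry12 lower (-1.05 ± 0.08), -0.10 for oligodendrocyte precursors with Pdgfra lower (-0.90 ± 0.07) and -0.06 for endothelium with 0 of 28 passing. The precursor list moved to -0.28 (percentile 0.33) with the best probe, -0.14 (2.31) with RefSeq mRNA probes and -0.24 (0.69) on array 1 alone, and the microglia list to -0.10 (2.42) with RefSeq mRNA probes.

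Of the 29 p53 targets 5 rose on the right and 1 fell. The 2 not yet given were Phlda3 at 1.33 ± 0.20 and Bbc3 at 0.96 ± 0.12. The list as a whole did not stand above random lists: its median was -0.09 (percentile 5.54), against a mean of 0.07 of the opposite sign. Bax and Mdm2 had 0.52 ± 0.01 and 0.22 ± 0.31 and did not pass. Mgmt was 1.86 ± 0.22 above control, the 1 of 22 DNA repair genes that passed (list median 0.01, percentile 64.8), and Fas was the 1 of 29 apoptosis genes (0.04, percentile 83.2). The reactive astrocyte and acute phase list had a median of 0.15 (percentile 99.7), with 4 of 27 members higher and Osmr, a cytokine receptor, lower at -0.88 ± 0.19. The 4 were Aspg at 1.17 ± 0.36, the iron-binding lipocalin Lcn2 at 1.16 ± 0.10, Gfap at 1.10 ± 0.11 and Cebpd at 1.03 ± 0.03. The 2 probes of Lcn2 read 0.33 and 1.98 on the right and, in the same order, 0.79 and -0.60 on the left. On array 2 alone the reactive astrocyte and acute phase list stood at percentile 88.9. The interferon list had a median of 0.09 (percentile 98.3), with Isg15 higher at 0.82 ± 0.13 and Ifit1 lower at -1.24 ± 0.49, and array 1 alone placed it at percentile 56.6 and the best probe per gene at 93.0. Antigen presentation stood at 0.13 (percentile 99.0), with RT1-CE16 at 0.90 ± 0.09 as the 1 of 23 genes that passed. Of 33 cytokine and chemokine genes Ccl3 rose, to 1.42 ± 0.10, and Cxcl11 and Ccl7 fell, by 0.84 (± 0.07) and 0.69 (± 0.04), though neither of the 2 probes of Ccl7 passed by itself; Ccl2 did not pass over its 3 probes but did by its RefSeq mRNA probe (1.81). The median of the list was 0.02 (percentile 74.6). Fos had a mean of -0.06 ± 0.43 and Hmox1, the haem oxygenase of oxidative stress, 0.06 ± 0.17, after 0.58 ± 0.08 on the left; neither value of Hmox1 passed.

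Of the top 12 genes above control on the right, Nrn1 (neuritin), a neurite growth factor, stood at 2.35 ± 0.07, the secreted olfactomedin Olfm1 at 1.95 ± 0.01 and the nuclear receptor Nr2f2 at 1.91 ± 0.18, beside Neurod2. The rest of the top 12 were Defb1, an epithelial defensin, at 3.89 ± 2.11, the small GTPase Rab25 at 2.97 ± 0.82, Tacc3 at 2.59 ± 0.73, Mptx1 at 2.30 ± 0.25, Kcnj13, a potassium channel of choroid plexus, at 2.13 ± 0.40, Otub2 at 2.12 ± 0.27, the sodium-proton exchanger Slc9a2 at 1.96 ± 0.23 and Zbtb46 at 1.88 ± 0.12. The 12 top-ranked below were Or5al1 (-2.83 ± 0.11), the mitotic kinesin Kif20b (-2.78 ± 0.41), Bbof1 (-2.63 ± 0.30), Fam50b (-2.43 ± 0.25), Ccdc63 (-2.34 ± 0.24), the linker histone H1f5 (-2.31 ± 0.41), Mid1 (-2.30 ± 0.53), Cstl1 (-2.17 ± 0.50), Smtnl2 (-1.96 ± 0.07), aromatase Cyp19a1 (-1.93 ± 0.19), Or13c3g (-1.84 ± 0.26) and Cd300c2 (-1.64 ± 0.07). All 12 were read by 1 probe each, as were the top 12 above control on the right and the 12 top-ranked below on the left. Of the 12 top-ranked above control on the left, Fas, Ccng1 and Cdkn1a had 2 probes and the rest, Mgmt among them, had 1. From the fixed lists the neuropeptides Cck and Vip passed upward at 1.5 ± 0.04 and 0.89 ± 0.04, the metabotropic receptors Grm8 and Gabbr2 at 1.29 ± 0.22 and 1.11 ± 0.00 and the nuclear receptor Nr4a2 at 1.14 ± 0.05. The neuropeptide Cartpt fell by 1.14 (± 0.04), the 1 of 23 thalamic, septal and hypothalamic markers that passed.

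In all, 1010 probes were higher and 814 lower on the right, and 255 genes were higher and 217 lower. Shuffling gave 1648 probes either way beside the 1824 observed, with the same fault as on the left, and array 1 alone gave 6524 higher and 4802 lower, array 2 alone 5350 and 7704. Where a passing probe's gene had other probes, these went the same way for 59.3% of 297 higher and 57.3% of 211 lower probes on the right, against 68.8% of 199 and 70.8% of 171 on the left. The 2 probes of Cdkn1a read 0.69 and 2.27 on the right and those of Fas 0.91 and 2.17. With RefSeq mRNA probes alone Lcn2 and Foxp1 no longer passed on the right, and Gpnmb (1.37) and Vcan (-0.97) did; with the best probe Bhlhe40 (0.66) and Scn4b (-0.66) did, and with centring Bhlhe40 and Tyms (0.61).

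**Figure D2:**
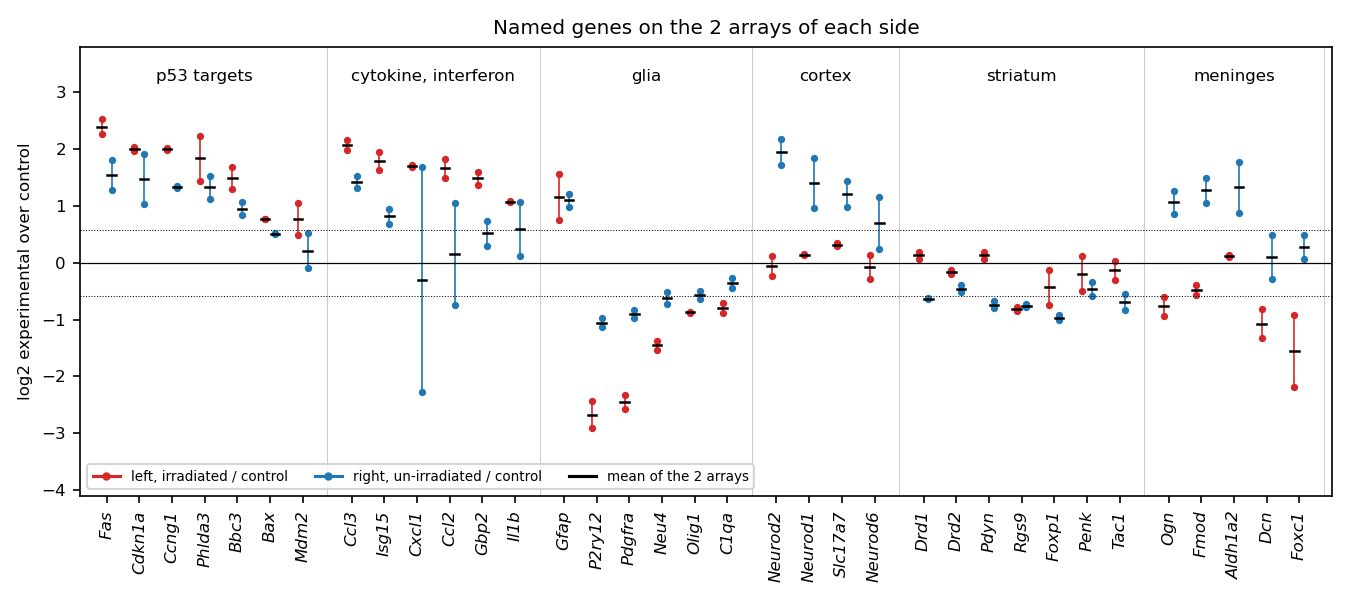
Log2 of experimental over control RNA for genes of the fixed lists, left side in red and right side in blue; dots are the 2 arrays of a side, black bars their mean, and dotted lines 1.5-fold. Fas, Cdkn1a and Ccng1 lay above 1.5-fold on all 4 arrays, Neurod2 on the right arrays with a left mean of -0.06, and Ogn went in opposite directions on the 2 sides.

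The third comparison sets the sides against each other. Genes above control in the irradiated striatum tended to lie above control in the un-irradiated one too: 102 of the 175 left-higher genes (58.3%) were above 0 on both right arrays, where 21.3% of all genes were, and their median right value was 0.40 against 0.95 on the left. Of 153 left-lower genes 45.8% were below 0 on both right arrays, against 21.6% of all genes. Taken from the right, sharing was weaker: 36.5% of the 255 right-higher genes were above 0 on both left arrays, with a median left value of 0.14, and 30.0% of the 217 right-lower genes below 0, against 23.0% of all genes each way. In all, 32 genes were higher on both sides, where independent lists would share 3.0. Another 20 were lower on both (2.23 expected) and 11 went opposite ways (5.17 expected). Neither the shares of all genes nor these expected counts measure chance. The dye effect, largely common to the sides, drives the 2 turned arrays of a side apart. Genes that pass on a side are picked for a small dye effect. They could therefore keep the same sign on the other side more often, in either direction. The shares going the opposite way are not given here. The medians rest on means of the 2 arrays, in which the dye largely cancels. Those top-ranked as higher on both sides were Mgmt, Bcl3, Fas, Ccng1, Ccl3, Phlda3, the chemokine Ccl19 (1.41 ± 0.05 left, 1.39 ± 0.34 right) and Olr621 (1.28 ± 0.19 and 1.86 ± 0.32). Those lower on both were P2ry12, Pdgfra, Rgs9, Krt28 (-1.42 ± 0.47 and -1.82 ± 0.60), the cytolinker Dst (-1.43 ± 0.34 and -1.50 ± 0.42), Ak8 (-1.32 ± 0.25 and -1.41 ± 0.13), Eaf2 (-1.01 ± 0.07 and -1.50 ± 0.32) and Fcrl2 (-0.87 ± 0.09 and -1.12 ± 0.03).

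Left minus right, the p53 list had a median of 0.50, above all random lists, with 3 of its 29 members passing upward. Ccng1 was 0.67 ± 0.03 higher on the left than on the right. The interferon list had 0.33, also above all random lists, with 7 of 32 passing, Gbp2 and Isg15 at 0.97 ± 0.11 and 0.97 ± 0.03. The cytokine list had 0.21 (percentile 99.97), with Ccl2 at 1.51 ± 0.72 and Ccl3 at 0.66 ± 0.01. Astrocyte markers differed by -0.22 (percentile 0.14), oligodendrocyte precursor markers by -0.21 (0.39), endothelial markers by -0.15 (0.33) and microglia markers by -0.11 (2.10). P2ry12 and Pdgfra differed by -1.62 ± 0.32 and -1.55 ± 0.06. Meningeal markers differed by -0.83 and cortex markers by -0.53, both below all random lists, and projection neuron markers by 0.20 (percentile 99.6), with Pdyn at 0.87 ± 0.01 and Drd1 at 0.76 ± 0.07. Oligodendrocyte markers did not separate the sides (0.00, percentile 40.9). Ranked by the smaller of their 2 array values, the top 8 genes higher on the left than on the right were Fam50b (3.88 ± 0.03), the drug-metabolising Cyp3a23-3a1 (3.64 ± 0.09), the kinase Ikbke (3.30 ± 0.09), Tnfsf9 (2.73 ± 0.57), Cstl1 (2.43 ± 0.01), Cd28 (2.36 ± 0.04), Or52e8 (2.73 ± 0.61) and Ttc4 (2.04 ± 0.03), although Ikbke, Cd28 and Ttc4 passed on neither side by itself. The top 8 the other way were Or10d5j (-3.16 ± 0.55), Washc4 (-3.49 ± 0.97), Or14c43 (-2.42 ± 0.11), Nrn1 (-2.32 ± 0.10), Vom2r78 (-2.31 ± 0.15), Defb1 (-4.06 ± 1.85), Mptx1 (-2.26 ± 0.13) and Clic2 (-2.42 ± 0.29).

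On single dye orientations the cytokine difference stood at percentiles 77.0 and 91.1, and on array 1 alone astrocyte markers at 2.99, endothelial markers at 2.69 and microglia markers at 8.24. On array 2 alone projection neuron markers stood at 90.6, and with RefSeq mRNA probes alone oligodendrocyte precursor markers at 3.40.

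Across sides 386 genes were higher on the left by the rule and 336 lower, and 1551 and 1276 probes. The left and right values correlated across probes, which are not independent replicates, at r = 0.154 (Spearman 0.205). Single arrays of opposite dye orientation, in which the dye effect is not cancelled, correlated at -0.694 and -0.716 (Spearman -0.326 and -0.242). These values include the 726 features that followed the dye on all 4 arrays, 0 of them with a gene. How much those features add to the single-array correlations was not tested. The sides have separate control RNAs, but the labels do not say whether these came from the same rats, so part of what the sides share may belong to the control animals.

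**Figure D3:**
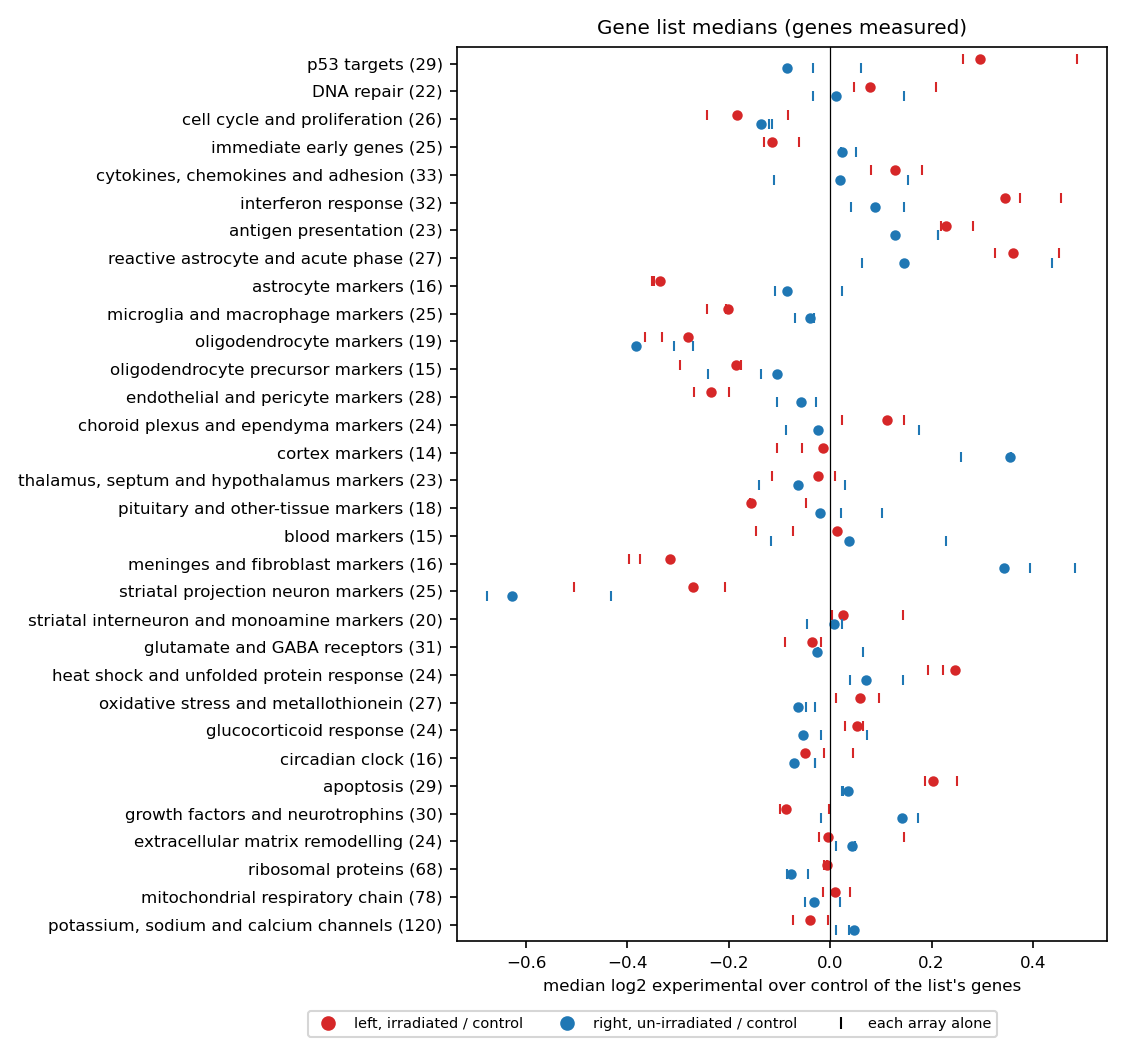
Median log2 of experimental over control RNA for 32 of the 34 fixed gene lists (olfactory receptors and keratins are not drawn), left side in red and right side in blue; dots use the mean of the 2 arrays and ticks each array alone, with the number of genes measured in brackets. The p53, interferon and reactive astrocyte medians on the left were 0.30, 0.34 and 0.36, and meningeal markers lay at -0.32 on the left and 0.34 on the right.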

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

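The weighing of the patterns below was chosen after the results were seen; the gene lists and the counting rule were not. Each side has 1 replicate, so none of these differences between sides was tested.

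Among named genes, 9 went past 1.5-fold in one direction on both left arrays and in the other on both right arrays. By left minus right these were Fam50b (3.88), Cyp3a23-3a1 (3.64), Alox12b (2.60), Akr1c2 (2.18) and Ggta1 (1.68), higher on the left and lower on the right, and Or10d5j (-3.16), Madcam1 (-2.80), Bpifb3 (-2.56) and Ogn (-1.83), lower on the left and higher on the right. Ogn and Ggta1 have more than 1 probe; the 2 probes of Ogn agreed on both sides (-0.92 to -0.61 left, 0.98 to 1.15 right), and the 3 of Ggta1 ranged from -1.98 to 0.65 on the right. The median of the meningeal and fibroblast list went the same opposite ways on each array alone, at -0.40 and -0.38 on the left and 0.48 and 0.40 on the right, a left minus right of -0.83.

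On the right, the cortex list lay above and the striatal projection neuron list below control by their medians, 0.98 apart against 0.26 on the left. A lower share of projection neurons with no other tissue added was predicted to raise every other cell type's markers alike. Oligodendrocyte markers had a right median of -0.38 instead, which goes against that prediction. They also had a median of -0.28 on the left, and each side is 1 pair of RNAs. Such a value also holds differences between single samples, so it does not decide about the explanation. More cortical tissue in the experimental sample than in its control is a candidate explanation that stays open. Neurod2 and Slc17a7 were 1.95 and 1.21 higher while Nrgn, which striatal neurons also express, was 0.06 and Emx2 -0.27, and the meningeal median was higher as well; the cortex median stood at percentile 99.9 on array 2 alone but 97.1 on array 1, short of the bound of 97.5 for each array, so the explanation missed the rule as first written, and the allowance for a miss smaller than the arrays differ, by which it stays open, was added after this value was seen. A change in the un-irradiated striatum itself, which the design names, was not tested.

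Genes higher on the irradiated left were often higher on the un-irradiated right. A fixed share of left RNA carried into the right sample would predict each right value from the left one; with the median share of 41.3%, the right value missed by over 0.2 the same way on both arrays for 17 of 48 precisely measured genes (35.4%), while 14.3% of 4405 such genes that did not pass on the left were as far from 0. Carry-over stays open, because each side is 1 pair of RNAs and such misses also hold differences between single samples. Control rats low in these genes on both sides cannot be told apart from a change in the irradiated rats, because each side has 1 control RNA: the 58.3% of left-higher genes above 0 on both right arrays would follow from either. A response of the un-irradiated side, which the design names, stays open and untested. Un-irradiated is the word of the labels. A dose is given for the targeted side alone, so any dose that reached the right striatum is unknown. Its part in these values was not tested.

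Olfactory receptor genes, which have no established role in striatum, passed at 1.46% on the left and 4.39% on the right, where 2.20% and 3.17% of all genes did. Probes near background with noisy ratios are a candidate explanation. The median half-range between the 2 left arrays was 0.29 for these 1094 genes. It was 0.05 for ribosomal proteins and 0.08 for respiratory chain genes, of which 0 of 146 passed on either side. The half-range holds the dye effect as well as noise, however. The olfactory receptor median was 0.13 on left array 1 and -0.27 on left array 2, and 0.20 and -0.27 on the right. As deposited this is red over green on all 4 arrays. A dye shift makes passing the same way on both arrays less likely, so the half-range does not show that noise made these calls. Spot intensities, which would show this directly, were not used here, and no biological explanation was tested.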

How the results depend on the processing

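The readings of the values as log2, without the 726 dye-following features, with RefSeq mRNA probes alone and with genes of 2 or more probes were chosen after seeing the data. Counts in this part run in 1 order: left higher, left lower, right higher, right lower, left minus right higher and lower, both sides higher, both sides lower, opposite. For probes, a 2-fold rule gave 162, 117, 271, 245, 572, 496, 24, 11 and 9, and a 1.3-fold rule 1351, 1400, 1846, 1607, 2835, 2439, 295, 250 and 131. Asking the mean of the 2 arrays alone to pass 1.5-fold gave 2470, 2069, 2966, 3613, 4643, 3599, 629, 552 and 616. Read as log2, the values gave 17, 7, 18, 25, 65, 71, 2, 0 and 0. Not turned, so that probes follow the dye, 2258 and 2000 passed on the left, 2877 and 2208 on the right, and 1015 and 1144 on both sides; dye-following probes thus outnumber RNA-following ones. A single array per side gave 4173 to 6269, 5031 to 5142, 5350 to 6524, 4802 to 7704, 5121 to 6738, 5046 to 5355, 2225 to 3094, 2590 to 2621 and 831 to 1091 probes, and 1048 to 1699, 1205 to 1364, 1320 to 1865, 1214 to 2281, 1344 to 2060, 1329 to 1522, 444 to 770, 529 to 649 and 185 to 232 genes. Without the 25% of probes with the largest half-range, 995 were higher on the left than the right, 58 lower on both sides and 28 opposite. For genes, taking the best probe gave 306, 273, 473, 387, 602, 572, 59, 43 and 34, and genes with 2 or more probes alone 40, 34, 52, 35, 108, 82, 8, 1 and 2; fewer genes enter the latter. Centring, scaling, quantile normalization, dropping the 726 features, the median over probes, RefSeq mRNA probes alone and dropping placeholder symbols kept each of these 9 counts within 1.5 times. The planned removal of values at 0 or at a shared extreme removed nothing, since none exist. The left-right correlation was 0.787 and 0.714 between arrays of the same dye orientation, -0.694 and -0.716 between opposite ones, 0.358 over probes of 1 sign per side and 0.205 by Spearman. Between single arrays the Spearman values were 0.528 and 0.434 for the same orientation and -0.326 and -0.242 for opposite ones. The olfactory receptor medians reversed on array 1 alone, to 0.13 on the left and 0.20 on the right, against -0.27 and -0.27 on array 2 alone. As deposited these are all red over green, the pattern of a dye effect. The growth factor median on the right reversed to -0.0176 on array 2 alone, against 0.17 on array 1. The cause of that reversal was not tested. Centring changed the side of the percentile bounds for 0 of 102 list medians. On array 1 alone 15 lost that side and 8 gained it, on array 2 alone 12 and 4, with RefSeq mRNA probes 5 and 9, with the best probe 4 and 9, with the median over probes 0 and 4 and with matched random lists 0 and 3. Of the named genes' calls, centring ended 3 and added 2, the median over probes 2 and 1, the best probe 2 and 9 and RefSeq mRNA probes 7 and 6. No paired analysis was possible because each group has 1 replicate and no result comes from a test. In the simulation, with 1 noise width for all probes, the rule missed most changes of 1.5-fold. Dim probes cannot be set apart without intensities.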

Other observations

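Several fixed lists outside the main themes held single genes that moved. In the extracellular matrix list (24 genes, medians 0.00 left and 0.04 right, the latter 0.15 at percentile 99.0 with the best probe) the phosphoprotein Spp1, made by activated phagocytes, was 1.65 ± 0.17 and the protease Adamts1 1.76 ± 0.50 higher on the left, and biglycan (Bgn) fell by 0.68 (± 0.00). Gadd45g, a stress-induced gene held by the glucocorticoid list (24 genes, 0.05 and -0.05), was 0.72 ± 0.01 higher on the left, beside Cdkn1a; the glucocorticoid-induced Fkbp5 and Sgk1 were within 0.1 of control on both sides. The circadian list (16 genes, -0.05 and -0.07) had Bhlhe40 higher on the left, at 0.66 ± 0.01. Oxidative stress genes (27, 0.06 and -0.06) had 0 passing on either side. In the blood list (15 genes, 0.01 and 0.04) the T cell gene Cd3e was 0.83 ± 0.12 higher on the left. In the pituitary and other-tissue list (18 genes, -0.16 at percentile 0.52 on the left, 4.14 and 34.4 on its arrays alone, and -0.02 on the right) the phosphatase Alpl fell by 0.76 (± 0.01) on the left and Fshb was 0.98 ± 0.16 on the right. The cortex list on the left had a median of -0.01 (percentile 41.5), with Emx2 lower at -0.68 ± 0.04, though neither of its 2 probes passed by itself, so that the best probe ended the call. The 68 ribosomal protein genes had medians of -0.01 and -0.08 (percentiles 40.8 and 1.49, the latter 5.19 and 17.2 on arrays 1 and 2 alone) and the 78 respiratory chain genes 0.01 and -0.03, with 0 passing.

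Of 120 potassium, sodium and calcium channel genes 6 rose and 0 fell on the right (median 0.05, percentile 99.4, but 29.3 and 97.3 on arrays 1 and 2 alone), among them Kcnip3 at 1.26 ± 0.02, Kcnj13 at 2.13 ± 0.40, Kcnj1 at 1.62 ± 0.68 and Kcna7 at 1.64 ± 0.72. On the left 1 passed, Scn4b at -0.72 ± 0.00 (median -0.04, percentile 5.23, but 1.26 on array 1 alone and 1.89 with RefSeq mRNA probes). Of 31 glutamate and GABA receptor genes 2 rose on the right, and Grin2c fell by 0.76 (± 0.16) on the left, a call that centring ended, with medians of -0.04 left and -0.03 right. In the interneuron and monoamine list (20 genes, 0.03 and 0.01) Cck and Vip rose on the right and the tryptophan hydroxylase Tph2 fell on both sides, by 0.86 (± 0.15) and 0.98 (± 0.32). Growth factors (30 genes) had medians of -0.09 (percentile 3.65) and 0.14 (99.8, and 97.4 on array 1 alone); the right median on array 2 alone was -0.0176, and Igf2, higher on the right, did not pass after centring. Right-side cell cycle genes (26, -0.14, percentile 1.05, but 2.83 and 16.1 on the arrays alone) had Aurkb at 1.12 ± 0.00 and Cdk1 at -0.70 ± 0.07, and right-side immediate early genes had a median of 0.02. Choroid plexus markers (24 genes) had medians of 0.11 (percentile 97.5, and 99.2 with the best probe) on the left with 0 passing and -0.02 on the right, where Kcnj13 and Igf2 rose and Mfrp fell by 1.79 (± 0.82); transthyretin (Ttr), the most abundant of them in that tissue, had 0.05 ± 0.04 and 0.67 ± 0.30 and did not pass, though its RefSeq mRNA probe did on the right (1.10). The thalamic, septal and hypothalamic list had medians of -0.02 and -0.06, the latter at percentile 1.81 on array 1 alone. Right-side heat shock genes had 0.07 (percentile 93.5, but 98.3 with the best probe, 99.6 with the median over probes and 99.5 with RefSeq mRNA probes), with Hspa1a at 0.77 ± 0.11. Of 41 keratin genes 2 fell on each side, with medians of -0.11 (percentile 0.58, and 39.2 on array 2 alone) and -0.05: Krt28 on both sides, Krt10 on the left at -0.88 ± 0.10 (3 probes from -1.69 to -0.27, with the call ended by their median and by the RefSeq mRNA probe) and Krt82 on the right at -0.67 ± 0.00. The 1094 olfactory receptor genes had medians of -0.07 and -0.04, 6 higher and 10 lower on the left, and 20 and 28 on the right.

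Over the 34 lists, 7 medians lay above the 97.5th and 12 below the 2.5th percentile of random lists on the left, and 7 and 5 on the right, where 1.70 lists outside the bounds would be expected by chance per side. Left minus right, the pituitary list had -0.18 (percentile 0.60, but 8.47 and 4.18 on the arrays alone, 7.11 with RefSeq mRNA probes and 3.47 with the best probe), growth factors -0.15 (0.25) and glutamate and GABA receptors -0.10 (1.79, but 31.0 on array 1 alone, 5.69 with RefSeq mRNA probes and 3.73 with the best probe). Inside the bounds as analysed, the difference went past them in 1 or more alternatives for the apoptosis, reactive astrocyte, antigen presentation, glucocorticoid, heat shock, choroid plexus and ribosomal lists upward and for the channel, keratin, matrix and immediate early lists downward. Median and mean differed in sign for the thalamic list on both sides, for the immediate early, cortex, circadian, matrix and ribosomal lists on the left, and for the p53, choroid plexus, pituitary, blood, receptor and glucocorticoid lists on the right. The lists overlap, and genes of 1 cell type vary together, so these counts describe the arrays and are not a test. Of passing probes whose gene had another probe, another one also passed for 24.6% and 16.4% of the higher and lower ones on the left and for 15.5% and 3.79% on the right.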
